A study of Mus musculus with 4 samples.

How the data were processed

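The series holds 4 Agilent mouse arrays of 62976 spots, of which 59305 are not controls and carry 55681 probes. Per the labels, each array holds total RNA of islets that were isolated with collagenase and a gradient and picked by hand. The labels do not say how many mice were pooled for an array, and no replicate number is given, so no paired analysis was possible. All 4 arrays lay on 1 slide and share a scan time. Values come from the deposited scanner files, whose unit is intensity on a linear scale per the file headers. The submitters' processing notes name Feature Extraction 9.5.1.1, whereas per the file headers the version was 10.7.1.1. The file headers' probe positions refer to mouse build mm9.

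The processed, background-corrected Cy3 intensity of each spot that carried no outlier flag was put on a log2 scale, and the 75th percentile of the non-control probes was subtracted from each array. A probe was measured in a comparison when its spot was well above background on both arrays by the scanner software's own call. Probes were assigned to genes through a RefSeq table of build GRCm38.p6, used only for names. By transcript accession 27235 features were named and by symbol or synonym 4146, 24300 kept the name in the file, and 3403 symbols differ from those in the file. Genes are the 22328 symbols found in that table, each represented by its probe with the highest mean level over the 4 arrays. The comparisons, the scaling, the background filter, the 2-fold threshold, the gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined.

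In the order male WT, male Tg, male Tg E2 and female Tg, the 75th percentile of processed intensity was 410, 230, 338 and 294, and the median 33.3, 23.6, 31.1 and 27.5. No spot was saturated, 115, 125, 103 and 111 spots carried an outlier flag, and the slopes of the spike-in series were 0.979, 0.995, 0.989 and 0.957. The log10 detection limits of that series were 0.951, 1.39, 0.680 and 0.847, so the limit was highest on the male Tg array. The scanner software's negative control metric was in its stated range only on the male Tg array. Spot noise was taken from 399 probes spotted 10 times. The standard deviation that it gives a difference of 2 arrays had a median of 0.0979 log2 for male Tg over male WT, 0.0957 for male Tg E2 over male Tg and 0.0945 for female Tg over male Tg. The scanner software's error model gave named genes a larger standard error, with a median of 0.21, 0.20 and 0.20 log2 in the same order and a highest value of 0.35 in each.

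Gene lists were written from general knowledge of islet biology. They are islet hormones, beta cell transcription factors, glucose sensing and secretion, beta cell disallowed genes, genes linked to dedifferentiation, alpha cell, delta cell, acinar, ductal, endothelial, stellate cell and matrix, macrophage, lymphocyte, adipocyte, Schwann and nerve and erythrocyte markers. The others are unfolded protein response, oxidative stress, S phase, G2 and M phase, cyclin kinase inhibitors and D cyclins, cAMP response and immediate early genes, estrogen response, prolactin response, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, fatty acid oxidation, interferon response, inflammatory genes, apoptosis, Reg family, hypoxia response and circadian clock. A list is described by the median log2 difference of its measured genes and by the percentile of that median among 10000 random lists of equal size, drawn from 20 bins of mean expression. It stands outside the random lists below percentile 2.5 or above percentile 97.5. In the 3 main comparisons 57 list medians did so, and 51 of these did so with the same sign under all 4 other scalings.

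Named genes are, per comparison, the 10 genes with the largest difference in each direction, up to 4 genes per list with the largest difference of at least 2-fold, and a fixed set of genes named whatever their value. That set is Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Ucn3, Aldh1a3, Crem, Esr1, Prlr, Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Genes of this rule that repeat a family or list already described are left out of the text, and a few others are not reported here. Genes named in the closing paragraphs, and Kdm6a, Eif2s3x and Tff1, were chosen after values were seen. Where several probes of a named gene were measured, the other probes had the opposite sign for 0 of 23 genes in male Tg over male WT, for 2 of 22 in male Tg E2 over male Tg and for 2 of 18 in female Tg over male Tg. In the same order, the probes of 3, 4 and 3 of these genes lay more than 1 log2 apart. Probe positions on mm9 are chr13:3940178-3940237 for Ucn3, chr5:148086570-148086629 for Pdx1, chr3:28627016-28627075 for Slc2a2, chr7:73535785-73535844 for Aldh1a3 and chr2:70439699-70439758 for Gad1. Exon or untranslated region was not assigned.

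The pipeline was tested on simulated data with known differences added to the measured noise. Genes made 4-fold different were called in 100% of cases in all 3 comparisons. Genes made 3-fold different were called in 100%, 98% and 98% of 50 cases, genes made 2-fold different in 52%, 44% and 56%, and genes made 1.5-fold different in 2%, 0% and 4%, in the order male Tg over male WT, male Tg E2 over male Tg and female Tg over male Tg. Of 14178, 14411 and 14003 unchanged genes 3, 0 and 3 were called, and of 200 unchanged lists 4%, 7% and 6%. All these rates hold for the simulated noise only. That noise includes no variation between mice, and the scanner software's error model gave named genes a larger standard error than spot noise did. The rates are therefore not rates of false calls for the comparisons of these arrays.

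The series matrix holds linear values that look quantile normalized, as the sorted columns differ from that of male WT by at most 0.0435% for male Tg, 0.0823% for male Tg E2 and 0.0294% for female Tg, with a median of 25.9 in each column and no centring, and it was used as an alternative. The others were median scaling, quantile normalization, normexp background modelling with quantile normalization in limma 3.58.1, a filter on all 4 arrays, no filter, a filter at each array's median, the mean of the probes of a gene, thresholds of 1.5-fold and 3-fold, and leaving out genes of other cell types. Shares of genes nearer to male WT were compared with 100 simulations in which only spot noise separated the arrays. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.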

Results

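Pancreatic islets of 24-week-old C57BL/6 mice were profiled on 4 one-colour Agilent mouse arrays, 1 array per group. The groups were wild-type males (male WT), transgenic males that the labels call diabetic (male Tg), transgenic males profiled 6 weeks after receiving an E2 implant (male Tg E2) and transgenic females (female Tg). E2 is the usual short name of estradiol, and the labels used here do not name the transgene. There were no replicates, so each difference is one between single arrays and not between conditions, no p-value is given, and the number of arrays limits precision. In the order male WT, male Tg, male Tg E2 and female Tg, 54.8%, 52.0%, 52.2% and 49.9% of spots were well above background, and 13888 genes were so on all 4 arrays. Across those genes the Pearson correlation of log2 levels was lowest between male WT and male Tg (0.900). It was 0.956 between male WT and male Tg E2, 0.960 between male WT and female Tg, and 0.968 between male Tg E2 and female Tg. Probes spotted 10 times had a median standard deviation between 0.0633 and 0.0740 log2 within an array, which is spot noise and not variation between mice. The scanner software's error model, which adds further array error, gave named genes a median standard error of 0.21, 0.20 and 0.20 log2 in the 3 main comparisons.

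Of the set chosen to check the sexes, Xist and 2 of 4 Y-linked genes followed the labels, and the other Y-linked genes gave too little signal. Xist, the RNA that silences an X chromosome in females, was well above background only on the female Tg array, and was at least 32.7-fold higher there than on the male Tg array. The Y-linked genes Ddx3y and Eif2s3y were well above background on the 3 male arrays and at least 22.4-fold and 31.2-fold lower on the female Tg array than on the male Tg array. An "at least" value of this kind sets the array with a clear signal against the background-limited signal of the other array, which is not well above background. Uty was above it only on the male Tg array, where it was at least 2.65-fold higher than on the female Tg array, and Kdm5d on none. X-linked genes that escape X inactivation, looked at after values were seen, were mixed. Kdm6a was 1.09 log2 higher on the female Tg array than on the male Tg array. Eif2s3x was lower (−2.19), with levels of 1.28, 0.92 and 1.14 on the male WT, male Tg and male Tg E2 arrays and −1.27 on the female Tg array. Its Y-linked copy Eif2s3y read 2.04, 1.53 and 1.94 on the same male arrays. Whether the Eif2s3x probe also detects Eif2s3y was not tested, so the lower value is not read as a sex difference of Eif2s3x. Esr1, which encodes estrogen receptor alpha, was not well above background on any of the 4 arrays.

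The comparison of male Tg with male WT asks what the transgene and the diabetes go with in male islets. The male Tg array differed from the male WT array in beta cell genes and in markers of other cells. The list medians of beta cell transcription factors and of glucose sensing and secretion were lower on the male Tg array, while those of genes that mature beta cells normally keep off and of genes linked to dedifferentiation were higher. The medians of acinar, connective tissue, lymphocyte and red cell markers were also higher, as were those of interferon response and inflammatory genes. Of 14382 genes well above background on both arrays, 2247 were at least 2-fold higher and 1249 at least 2-fold lower on the male Tg array, together 24.3%. At 4-fold the counts were 1001 higher and 164 lower, whereas at 1.5-fold more genes were lower (3615) than higher (3180). A further 746 genes were at least 2-fold higher and 121 at least 2-fold lower by an "at least" value. The median difference of all measured genes was −0.21 log2, and relative to that median 2643 genes were at least 2-fold higher and 752 lower.

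Among 13 measured beta cell transcription factors, 8 were at least 2-fold lower, 5 lay between and none was higher, with a median difference of −1.13 log2 that was lower than in all 10000 random lists of matched expression. Random lists serve throughout as a description of these arrays and not as a test of conditions. Nkx6-1, which maintains beta cell identity, differed by −2.14 log2, the endocrine factors Insm1 and Neurod1 by −1.67 and −1.61, and Pdx1 by −1.51, a 2.84-fold lower level. Mafa, which activates the insulin genes in mature beta cells, was at −0.99. Of 27 genes for glucose sensing and secretion, 13 were lower and none higher (median −0.87 log2). They included Sytl4, whose product sits on insulin granules (−3.57), G6pc2, the islet glucose-6-phosphatase (−2.68), and the glucose transporter gene Slc2a2 (−2.24, 4.73-fold lower). Ucn3, a peptide gene that marks mature beta cells, was 21.0-fold lower and the cation channel gene Trpm5 19.5-fold lower. In each comparison, the 10 highest and 10 lowest genes are those among genes with an established symbol that were well above background on both arrays. The lowest was Gad1, which encodes a GABA-synthesizing enzyme and was 55.7-fold lower. Others among the 10 lowest genes were Cib3 (−5.37), T2 (−5.12), Fbxo16 (−4.08), Olfr97 (−4.02), the cytochrome oxidase subunit gene Cox6a2 (−3.98), Azin2 (−3.90) and Amer2 (−3.83). For Fbxo16 and Azin2 another probe of the same gene gave a much smaller difference in male Tg E2 over male Tg, as given below. In male Tg over male WT the median of 29 acinar markers was 4.48 log2 and that of 12 lymphocyte markers 3.18.

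**Figure D1:**
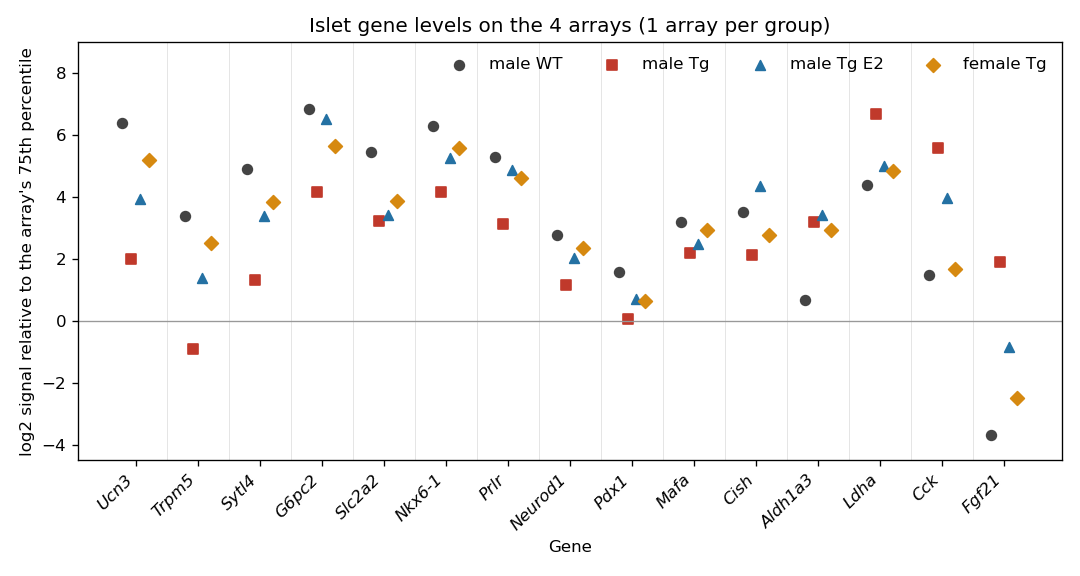
Log2 level, relative to the 75th percentile of each array, of 15 genes on the 4 arrays. Ucn3 reads 6.40 on the male WT, 2.01 on the male Tg, 3.93 on the male Tg E2 and 5.19 on the female Tg array, whereas Aldh1a3 reads 0.68, 3.21, 3.41 and 2.95.

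Genes that beta cells normally repress were higher, as were markers of other cells, with medians of 3.10 for matrix genes and 4.48 for acinar markers in the same comparison. Of the 14 disallowed genes 3 are also on other lists. Of 13 measured disallowed genes, 11 were at least 2-fold higher (median 2.44 log2), among them Cxcl12 (3.23), the transcription factor gene Maf (3.22), Igfbp4 (2.84) and Ldha, which encodes a lactate dehydrogenase subunit (2.30). Of 7 genes linked to dedifferentiation, 5 were higher (median 2.61), with Fgf21 at 5.58, the gut peptide genes Gast and Cck at 4.35 and 4.09, and Aldh1a3 at 2.53. Aldh1a3 encodes a retinaldehyde dehydrogenase found in failing beta cells. Of 11 alpha cell markers, 5 were higher and none lower (median 0.76), led by the amino acid transporter gene Slc38a5 (3.76) and the alpha cell factor gene Irx2 (1.55). Of 5 delta cell markers 3 were higher, with Hhex at 1.75 (median 1.25). The alpha and delta medians kept their sign under all scalings, at 0.22 and 0.79 after quantile normalization and 0.20 and 0.50 after normexp. The alpha median did not stand outside the random lists after quantile normalization, with or without background modelling, or with the series matrix values, and the delta median did not after background modelling with quantile normalization. The islet hormone genes depended on scaling, with a median of 0.79 over 8 genes after 75th percentile scaling and −0.21 after quantile normalization. Ins1 stood at 0.67 and Ins2 at 0.73 in the former and at −0.25 and −0.29 in the latter, so no direction is given for them. Gcg (0.76 and −0.26) and Ppy (0.82 and −0.18) changed sign in the same way, whereas Sst (1.25 and 0.27) kept its sign, and so did Ghrl, which was at 1.72 and 1.86.

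Acinar and Reg genes were 6 of the 10 highest genes. The calcium-binding protein gene S100g was 967-fold higher and led the list. It was followed by the secreted lectin gene Reg3g (152-fold), Itih4 (140-fold), Reg3d (98.9-fold) and the acinar gene Cuzd1 (77.2-fold). Of 29 acinar markers 27 were higher, including the protease gene Ctrc (6.18), the acinar transcription factor gene Rbpjl (6.11) and the ribonuclease gene Rnase1 (5.98). The water channel gene Aqp12 (6.08) and Pdia2 (5.91), outside the list, completed the 10 highest genes. Among genes not well above background on the male WT array, Tff1 was at least 7.02 log2 higher and the adipocyte gene Cfd at least 6.88. Tff1 is on the estrogen response list. All 7 Reg genes were higher, with a median of 5.28. Of 10 ductal markers 5 were higher and 1 lower (median 0.71, and 1.45 without the background filter or with only genes above each array's median), with Tff2 at 5.86 and the keratin gene Krt19 at 3.21. Stellate cell and matrix genes were higher in 16 of 17 cases (median 3.10), with the collagen genes Col1a1 and Col3a1 at 4.52 and 4.24. Lymphocyte markers were higher in 10 of 12 cases, including Jchain (4.50), Ms4a1 (3.70) and Cd79b (3.61), which are B lineage genes, and Cd2 (3.69). The macrophage median was 1.56, with 12 of 19 genes higher, Ptprc at 2.99 among them. All 7 erythrocyte markers were higher (median 2.23), with the globin gene Hbb-bs at 2.36. The endothelial median was 0.35 with 2 of 12 genes higher, and it did not stand outside the random lists after quantile normalization, with or without background modelling, or with the series matrix values. Only 1 adipocyte marker, Fabp4, was measured on both arrays (1.71), and the median of 4 Schwann and nerve markers was 0.69, with S100b at 2.33.

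Immune signalling genes stood with these cell markers. Of 19 interferon response genes 13 were higher and none lower (median 1.31), with the antiviral genes Isg15 (3.10) and Gbp2 (2.10) and the chemokine gene Cxcl10 (2.12). Of 12 inflammatory genes 9 were higher (median 1.31), led by the chemokine genes Ccl2 (3.42) and Cxcl1 (3.23). The apoptosis list had 5 of 11 genes higher (median 0.84), among them Pmaip1 (1.94) and Bcl2 (1.92), and its median was 0.46 after normexp, without the background filter and with only genes above each array's median. Genes of G2 and M phase were higher in 9 of 12 cases (median 1.72), with Mki67 at 1.97 and Ccnb1 at 2.28, and their median was 0.80 after normexp. The S phase median was 0.45 with 5 of 16 genes higher.

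Stress and metabolic lists showed smaller differences in this comparison. The median of 23 unfolded protein response genes was −0.05 log2 with 1 gene, Atf3, higher (1.99), and that of 15 oxidative stress genes was 0.03 with Gpx3 higher (2.30). Oxidative phosphorylation genes had a median of 0.06, a sign that depended on scaling, with 30 of 31 genes between the 2-fold limits. Glycolysis genes had a median of 0.33 that turned to −0.0082 after quantile normalization, with 3 of 18 genes higher and 2 lower. Circadian clock genes had a median of −0.71, at percentile 0.7 of the random lists, with 3 of 11 lower, including Per2 (−1.38) and Ciart (−1.39). Cholesterol and fatty acid synthesis genes had a median of −0.42, with 6 of 21 lower, among them the regulator gene Srebf1 (−1.61), and Scd1 higher (2.35). Fatty acid oxidation had a median of 0.02 with 4 of 14 genes higher. The hypoxia response list had a median of −0.30 with 3 of 10 genes higher, Car9 (3.20) the most, and 2 lower, including Vegfa (−1.50), and that of cyclin kinase inhibitors and D cyclins −0.46 with Ccnd2 lower (−1.53). Prolactin response genes were lower in 4 of 10 cases (median −0.34), with the receptor gene Prlr at −2.17, the feedback inhibitor gene Cish at −1.37 and, in the other direction, the serotonin-synthesis gene Tph1 at 2.52. Estrogen response genes had a median of 0.37 with 2 of 9 higher, including Gper1 (2.11), and Tfrc lower (−1.34). The 9 leave out Stc2 and Tff1, which were not well above background on the male WT array. Stc2 was at least 4.07 log2 higher, and the value of Tff1 is given above. The cAMP and immediate early list had a median of −0.34 with Sik1 higher (1.19) and Crem at −0.21.

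The comparison of male Tg E2 with male Tg asks what the implant goes with in transgenic males. The list medians of beta cell transcription factors and of secretion genes were higher on the male Tg E2 array, although most genes of these lists lay between the 2-fold limits and the insulin genes depended on scaling. The medians of interferon response, inflammatory, lymphocyte and red cell genes were lower. Matrix and alpha cell medians lay inside the random lists. Of 14616 measured genes 372 were at least 2-fold higher and 1170 lower on the male Tg E2 array, together 10.6%, and at 4-fold the counts were 39 and 253. By an "at least" value a further 95 were higher and 256 lower. The median difference of all measured genes was 0.12 log2, and relative to it 255 genes were higher and 1361 lower.

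The beta cell transcription factors had a median of 0.71 log2, higher than in all random lists, with 2 of 13 genes at least 2-fold higher (Nkx6-1 at 1.11 and Rfx6 at 1.02) and 11 between. Pdx1 was at 0.63 and Mafa at 0.27. The secretion list had a median of 0.52 with 6 of 27 genes higher and none lower, including G6pc2 (2.33), Trpm5 (2.30) and Sytl4 (2.07). Ucn3 was 1.92 log2 higher, whereas Slc2a2 differed by only 0.19. The potassium channel gene Kcnk9 was the highest gene (19.8-fold), and Fyb2 (3.26), the calcium-binding protein gene S100z (3.14), Galnt18 (2.90), Mdm1 (2.85), Rims3 (2.78) and Cib3 (2.77) were among the 10 highest. For Azin2 (3.15), Zdhhc22 (2.85) and Fbxo16 (2.69), also among them, another probe for the same gene read 0.07, −1.39 and −0.07. Disallowed genes had a median of −0.82 with 3 of 14 lower, namely Ldha (−1.69), Maf (−1.60) and Cxcl12 (−1.45). Dedifferentiation genes had a median of −0.61 with 3 of 8 lower, Fgf21 (−2.75), Cck (−1.60) and Gast (−1.21), while Aldh1a3 was at 0.20. The acinar median was −0.69 beside these, with 7 of 29 genes lower, and it was nearer to 0 after quantile normalization (−0.22) and normexp (−0.28) and with the series matrix values (−0.22). Prolactin response genes were higher in 4 of 10 cases and lower in 2 (median 0.64, and 0.43 after normexp). Cish was 4.63-fold higher, Prlr at 1.73 and Socs2 at 1.21, and Tph1 was at −1.81. Estrogen response genes had a median of −0.02 with 1 of 10 higher, Greb1 (1.04), a known target of the estrogen receptor. The 10 leave out Tff1, which was not well above background on the male Tg E2 array. Its "at least" value, given below, was lower.

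Apol10a was the lowest gene (26.0-fold lower), and the complement factor gene Cfd (−4.47), which is on the adipocyte list, the granulocyte gene Mpo (−3.76), the platelet genes Ppbp (−3.70), Gp9 (−3.67) and Gp1ba (−3.57), Aqp3 (−3.57), Tdh (−3.51), the haem-synthesis gene Alas2 (−3.57) and the globin gene Hbb-bt (−3.51) made up the rest of the 10 lowest. Tff1, on the estrogen response list and not well above background on the male Tg E2 array, was lower by at least 6.50 log2. All 7 erythrocyte markers were lower (median −3.32). Lymphocyte markers were lower in 9 of 11 cases (median −1.84), with Jchain at −2.66 and Cd3g at −2.21, and macrophage markers in 7 of 19 (median −0.24). Interferon response genes were lower in 12 of 20 cases and higher in none (median −1.26), led by Cxcl10 (−2.53), Isg15 (−2.33), Oasl2 (−2.12) and Oas1a (−2.05). Inflammatory genes were lower in 7 of 11 cases and higher in 1 (median −1.31), with Ccl2 at −2.42 and Cxcl1 at −1.98. The inflammatory median was −0.87 after normexp. The apoptosis median was −0.34 with 3 of 11 genes lower. Reg genes had a median of −1.47 with 4 of 7 lower, Reg3a most of all (−2.53), and Rbpjl was the lowest of the acinar markers (−1.97), of which 22 of 29 lay between the 2-fold limits.

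Other lists differed less on the male Tg E2 array. The medians were −0.01 for matrix genes and 0.23 for alpha cell markers, each with 1 gene lower, and those of ductal (0.03, with 3 of 11 lower) and endothelial (0.03, with 1 of 12 lower) markers turned negative under median scaling. None of these stood outside the random lists. The delta cell median was −0.24, positive after quantile normalization, and the islet hormone median was −0.41, which became 0.12 after quantile normalization. After 75th percentile scaling Ins1 was at −0.52, Ins2 at −0.48, Gcg at −0.47, Sst at −0.35 and Ppy at −0.07, and after quantile normalization at 0.25, −0.03, −0.02, 0.14 and 0.36. Crem was at −0.17. Schwann and nerve markers lay inside the random lists. Glycolysis had a median of −0.31 with 3 of 19 genes lower, oxidative phosphorylation −0.14 with all 31 between, cholesterol and fatty acid synthesis −0.13 with 2 of 21 lower, and G2 and M phase −0.51 with all 13 between. After normexp the glycolysis median was −0.0948, that of oxidative phosphorylation −0.0853 and that of G2 and M phase −0.27, and after quantile normalization glycolysis was at −0.16. Fatty acid oxidation was at 0.13, hypoxia response at 0.12 with Bnip3 higher (1.59) and Car9 lower (−1.11), and circadian genes at −0.08 with Ciart higher (1.03), all inside the random lists. So were the oxidative stress, cyclin and cAMP lists and the unfolded protein response, in which Atf3 was lower (−1.16). The S phase median of −0.19, with Tk1 lower (−1.35), was inside them at percentile 3.2 but outside after quantile normalization (1.9) and normexp (0.94) and with the series matrix values (1.91).

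The comparison of female Tg with male Tg asks how transgenic mice of the sexes differ. The list medians of beta cell transcription factors and of secretion genes were higher on the female Tg array, although most genes of these lists lay between the 2-fold limits, and those of acinar, Reg, ductal and matrix genes were lower. The lymphocyte median lay inside the random lists. Of 14207 measured genes 499 were at least 2-fold higher and 1217 lower on the female Tg array, together 12.1%, and at 4-fold the counts were 20 and 460. By an "at least" value a further 114 were higher and 383 lower. The median difference of all measured genes was 0.10 log2, and relative to it 361 were higher and 1383 lower. Sex and any effect of the transgene in each sex cannot be separated here, as there was no wild-type female array.

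Beta cell transcription factors had a median of 0.76 log2 with 4 of 13 higher, among them Nkx6-1 (1.44), Neurod1 (1.19) and Pax6 (1.16), and 1 lower, Hnf4a (−1.34). Pdx1 was at 0.58 and Mafa at 0.72. The secretion list had a median of 0.64 with 10 of 27 genes higher and none lower, including Trpm5 (3.42), also among the 10 highest, and the incretin receptor gene Gipr (1.95), with Slc2a2 at 0.64. Ucn3 was 9.04-fold higher. The 10 highest genes also held Cib3 (3.62), Amer2 (2.99), the transcription factor gene Sox5 (2.80), Fam151a (2.58) and Kcnk9 (2.45), besides Cox6a2 and Sytl4. Disallowed genes had a median of −0.98 with 6 of 13 lower, including Mgst1 (−2.14), Ldha (−1.84), Maf (−1.70) and Tst (−1.62). Dedifferentiation genes had a median of −0.96 with 3 of 7 lower, Fgf21 (−4.39), Cck (−3.88) and Gast (−3.35), while Aldh1a3 was at −0.26. The acinar median beside these lists was −3.95, with 27 of 29 genes lower.

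Reg2 was the lowest gene (139-fold lower), followed by Reg3d (−6.76), Reg3a (−6.25) and Reg3g (−6.22), and all 7 Reg genes were lower. The acinar genes Cuzd1 (−6.17), Ctrc (−6.03), Rbpjl (−5.91) and Pnliprp2 (−5.85) and the genes Itih4 (−6.07) and Aqp12 (−5.86) made up the rest of the 10 lowest. Ductal markers were lower in 6 of 10 cases (median −1.34), with Tff2 at −5.22 and Krt19 at −3.91, and matrix genes in 12 of 20 (median −1.09), with Acta2 at −2.68 and Col1a1 at −1.99. All 7 erythrocyte markers were lower (median −1.45), with Hba-a1 at −1.97. Both measured adipocyte markers, Cfd (−4.97) and Fabp4 (−1.48), were lower. Lymphocyte markers had a median of −0.09 with 2 of 13 lower, Cd4 (−1.18) and Jchain (−1.15), and macrophage markers −0.30, or −0.19 after normexp, with 2 of 19 lower. Interferon response genes were lower in 7 of 19 cases and higher in 1 (median −0.65), with Isg15 at −2.09 and Ifit1 at −1.81. Inflammatory genes were lower in 4 of 12 cases (median −0.87), with Ccl2 at −1.91 and Lcn2 at −1.89. The apoptosis list had a median of −0.59 with 3 of 11 lower and Bax higher (1.25).

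Cholesterol and fatty acid synthesis genes had a median of 0.29, inside the random lists, with Srebf1 (1.22) and Insig1 (1.04) higher and none lower. Fatty acid oxidation had a median of −0.40 with 3 of 14 lower, among them Angptl4 (−2.44), and glycolysis −0.47 with 2 of 18 lower. Oxidative phosphorylation stood at −0.26 with all 31 genes between, and at −0.0491 after quantile normalization. Unfolded protein response genes had a median of −0.17 with 3 of 23 lower, including Atf3 (−2.55), and oxidative stress genes −0.29 with 3 of 15 lower. The latter lay inside the random lists at percentile 2.77 but outside after quantile normalization (0.32) and normexp (0.295) and with the series matrix values (0.32). Estrogen response genes had a median of −0.21 with 3 of 11 lower, namely Stc2 (−2.21), Gper1 (−1.76) and Greb1 (−1.02). Prolactin response genes stood at 0.28 with Prlr (1.49) and Ivd (1.01) higher and Ehhadh lower (−1.44). Car9 was the lowest (−3.89) of 3 lower hypoxia genes out of 10, whose median of −0.01 changed sign with scaling. G2 and M phase genes had a median of −0.49 with all 13 between, which was −0.30 after normexp and −0.29 without the background filter. Circadian genes (0.21), alpha cell markers (0.07, with 1 of 11 lower), endothelial markers (−0.12, with 1 of 12 higher and 2 lower), delta cell markers (−0.01, positive after quantile normalization) and the S phase, cyclin, cAMP and Schwann lists lay inside the random lists. The islet hormone median was −0.36 and became 0.37 after quantile normalization. After 75th percentile scaling Ins1 was at −0.55, Ins2 at −0.64, Gcg at −0.47, Sst at −0.29 and Ppy at 0.27, and after quantile normalization at 0.25, 0.18, 0.37, 0.46 and 0.99. Crem was at 0.11.

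**Figure D2:**
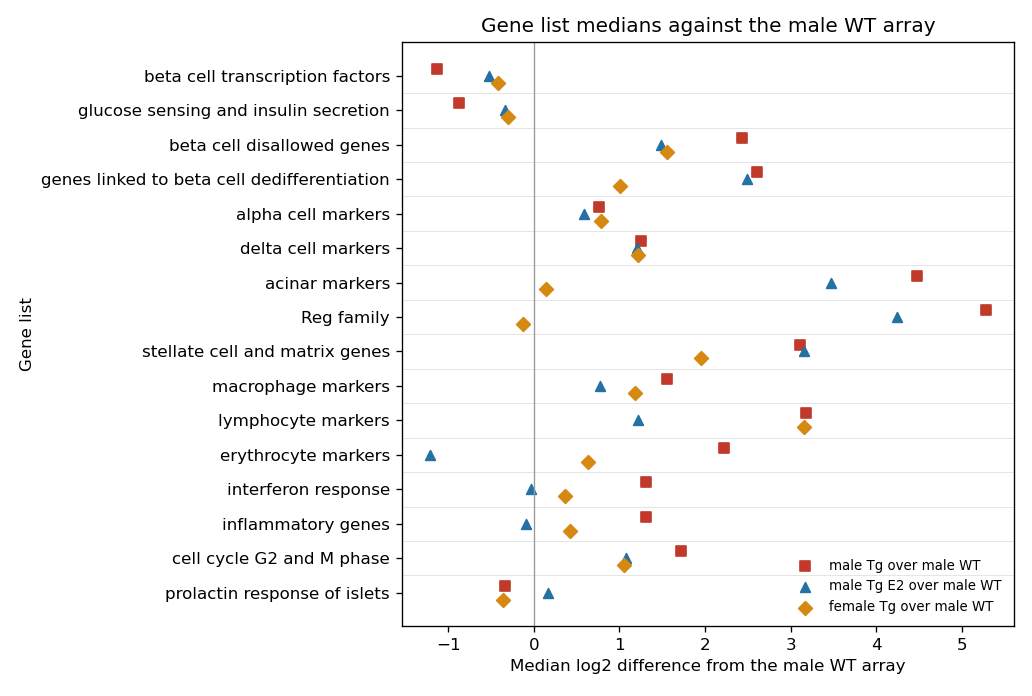
Median log2 difference from the male WT array of 16 gene lists on the male Tg, male Tg E2 and female Tg arrays. Beta cell transcription factors read −1.13, −0.53 and −0.42 in that order, disallowed genes 2.44, 1.49 and 1.55, and acinar markers 4.48, 3.47 and 0.15.

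Most genes that set the male Tg array apart from the male WT array lay nearer to the male WT level on the other transgenic arrays. Of 3441 genes at least 2-fold apart between male Tg and male WT and measured on the male Tg E2 array, 3199 (93.0%, 95% interval 92.1% to 93.8%) were nearer to male WT there. As the genes were picked on the male Tg array, some return is built in, and spot noise alone gave 54.2% in 100 simulations. Differences between individual mice add to the built-in return, are not part of that figure and cannot be measured with 1 array per group, so the share is not read as an effect of the implant or of sex. Nearer was not the same as level with male WT, as 2009 of these genes (58.4%) were less than 2-fold from it. The 2192 higher genes had a median of 1.89 log2 on the male Tg array and 1.05 on the male Tg E2 array, and the 1249 lower genes −1.28 and −0.65. On the female Tg array 3023 of 3331 genes (90.8%, 89.7% to 91.7%) were nearer to male WT, against 54.2% from spot noise, and 2051 (61.6%) were less than 2-fold from it. The higher genes went from a median of 1.88 to 0.86 and the lower genes from −1.28 to −0.65. The interval treats genes as independent, which they are not.

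Of all genes lower on the male Tg array, 97.9% were nearer to male WT on the male Tg E2 and 96.1% on the female Tg array, and of all higher genes 90.1% and 87.6%, so a list in which all genes were nearer is close to these shares. All 8 beta cell transcription factors that were lower on the male Tg array were nearer to male WT on each of the other transgenic arrays, and so were all 13 secretion genes. Of the 8 transcription factors, 7 were within 2-fold of male WT on the male Tg E2 array and 8 on the female Tg array. Of the 13 secretion genes, 6 and 8 were. All 11 disallowed genes were nearer, but only 2 on the male Tg E2 and 4 on the female Tg array came within 2-fold. All 13 interferon genes were within 2-fold of male WT on the male Tg E2 array, and 8 on the female Tg array. Acinar genes, 27 in number, came within 2-fold in 1 case on the male Tg E2 array and in all 27 on the female Tg array. Of 16 matrix genes 8 were nearer on the male Tg E2 array and 16 on the female Tg array. Of 5 alpha cell genes 1 was nearer on each.

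**Figure D3:**
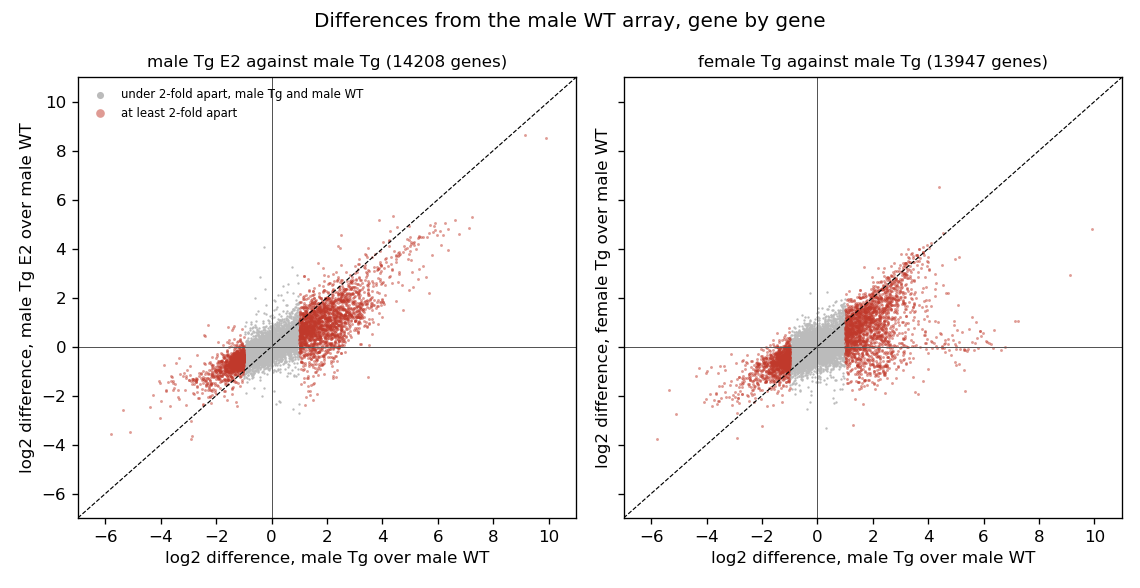
Log2 difference of male Tg from male WT (horizontal) against that of male Tg E2 (left, 14208 genes) and female Tg (right, 13947 genes) from male WT (vertical), with the line of equality dashed and genes at least 2-fold apart in male Tg in red. Most red points lie between the dashed line and zero, 93.0% of them nearer to male WT on the male Tg E2 array and 90.8% on the female Tg array.

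The male Tg E2 and female Tg arrays shared many of the genes set apart from male Tg. Among 14071 genes measured in both comparisons, 607 were at least 2-fold lower in both, of 1028 and 1206, where independence gives 88.1 and spot noise 0.58. At least 2-fold higher in both were 142, of 359 and 494, against 12.6 and 0.51. The correlation of the differences was 0.689 against 0.576 from spot noise, and their covariance 0.375 against 0.0120. Both comparisons use the same male Tg array, so part of the excess may come from that array, this part cannot be split off with 1 array, and the excess is not called a shared effect.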

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

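Array features that carry no gene name in the RefSeq table were set aside from the gene counts, and many of them differed. Of 5086 such features measured in male Tg over male WT, 582 were at least 2-fold higher and 448 lower. In male Tg E2 over male Tg 170 of 5060 were higher and 339 lower, and in female Tg over male Tg 252 of 4820 were higher and 445 lower. The largest difference upwards in male Tg over male WT was at chr9:78372153-78372834 of mm9, with 7.49 log2 (180-fold), and the largest downwards at chr7:77481448-77495548, with −4.41 (21.2-fold lower). What these features measure was not analysed here.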

How the results depend on the processing

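Among list medians that stood outside the random lists, 8 values under an alternative had the opposite sign, all through scaling. Islet hormones in male Tg over male WT turned to −0.21 after quantile normalization, −0.13 after normexp and −0.22 with the series matrix values, and in male Tg E2 over male Tg to 0.12, 0.043 and 0.11. Glycolysis in male Tg over male WT turned to −0.0082 after quantile normalization and −0.0075 with the series matrix values. Spots of Ins1, Ins2, Gcg and Ppy lie near the top of the intensity scale, where quantile normalization forces the arrays to share values. In male Tg over male WT, Sst and Pyy, which lie there too, kept their sign after quantile normalization at smaller values (0.27 and 0.39). Ghrl lies lower and kept its sign as well. The 75th percentile of log2 signal was 8.51 on the male WT array and 7.66 on the male Tg array. Subtracting it raises every difference of male Tg over male WT, so both scalings shape the sign. Which of them gives the right sign of the hormone genes cannot be decided here. Of the other list medians 785 stayed within spot noise and 172 moved, and 19 and 13 of these, all of lists inside the random lists, changed sign. Of the named-gene differences 2545 stayed and 508 moved, and 33 of the latter changed sign, all from differences under 2-fold, such as Ins1, Ins2, Gcg and Ppy in male Tg over male WT. Counts of genes at least 2-fold apart moved as follows. Normexp, which adds an offset that shrinks weak signals, gave 690 lower in male Tg over male WT, 192 higher and 770 lower in male Tg E2 over male Tg, and 272 higher in female Tg over male Tg. Its shares nearer to male WT were 94.98% for male Tg E2 and 92.3% for female Tg. Without the background filter, which admits more genes by construction, 4369 were higher in male Tg over male WT, 908 higher and 2466 lower in male Tg E2 over male Tg, and 1098 and 2678 in female Tg over male Tg. The shares were 89.0% and 89.0%. With only genes above each array's median, 1240 were higher in male Tg over male WT, 242 higher and 750 lower in male Tg E2 over male Tg, and 327 higher in female Tg over male Tg, with shares of 94.7% and 93.0%. The 1.5-fold threshold gave 3180 higher and 3615 lower in male Tg over male WT, so that 46.8% of the genes past it were higher, against 64.3% at 2-fold. It gave 1658 higher and 2071 lower in male Tg E2 over male Tg, and 2031 and 2192 in female Tg over male Tg. The 3-fold threshold gave 1416 higher and 338 lower, 90 and 530, and 61 and 664 in the same order, and a share of 94.8% for male Tg E2. Including unnamed features, an alternative chosen after seeing the data, gave 751 higher in female Tg over male Tg. A threshold sets its counts by construction, and for the shares the cause was not tested. A block for the slide was not run, as all 4 arrays lay on 1 slide.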

Other observations

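The female Tg and male Tg E2 arrays can be compared directly, with 457 genes at least 2-fold higher and 620 lower on the female Tg array. On the female Tg array acinar markers had a median difference of −3.25 log2 from the male Tg E2 array, Reg genes −4.26 and matrix genes −1.12. The medians of lymphocyte markers (1.76), erythrocyte markers (1.65) and interferon response genes (0.53) were higher, which does not hold for every gene of these lists. The platelet genes Ppbp (2.99), Gp1ba (2.43) and Gp9 (2.41) were higher on the female Tg array and the kallikrein gene Klk1 lower (−4.57). Genes linked to dedifferentiation had a median of −1.12, with 4 of 7 at least 2-fold lower and 3 between, and the prolactin feedback inhibitor gene Cish was lower (−1.57). On both arrays Gad1 stayed lower than on the male WT array (−3.57 for male Tg E2, −3.79 for female Tg), and S100g stayed higher (8.50 and 4.81).

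All tests in this part were chosen only after the results were seen. Acinar markers and Reg genes were higher on the male Tg array than on the male WT array and much lower on the female Tg array. Acinar tissue carried over with picked islets cannot be told apart from other causes, since the 9 of the 10 brightest acinar markers that were at least 2-fold higher (range of all 10, 0.76 to 4.59 log2) restate the pattern, and 29 of 32 list genes were already well above background on the male WT array. In male Tg E2 over male Tg the Reg median of −1.47 lay outside the range of −1.04 to −0.56 for medians of 7 acinar markers. Single genes overlapped, as Reg genes ranged from −2.53 to −0.49 and acinar markers from −1.97 to −0.44. At least 2-fold lower were 4 of 7 Reg genes and 7 of 29 acinar markers. In male Tg over male WT the Reg median of 5.28 also lay outside the range for medians of 7 acinar markers, 2.92 to 5.04. Single genes overlapped there too, with Reg genes from 2.52 to 7.25 and acinar markers from 0.76 to 6.27. Whether signal level explains the gap between the medians was not tested in either comparison. Whether the amount of Reg transcript per acinar cell was unchanged is therefore not settled. Neither list shares genes with another list. Induction of Reg genes or a difference in the exocrine tissue of these mice stays open and was not tested.

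Lower beta cell genes on the male Tg array may reflect fewer beta cells, scaling or lower expression per cell. A smaller share of beta cells alone would lower genes expressed only in beta cells alike. Pdx1, Mafa, Nkx6-1, Slc2a2, G6pc2 and Ucn3 spread over 3.40 log2, from −0.99 to −4.39. These 6 genes were picked with their values known. Whether each is expressed only in beta cells in these islets was not tested, so the spread does not settle the question. Ins1 and Ins2, not among the 6, differed far less than Ucn3. They were at 0.67 and 0.73 under the main scaling and at −0.25 and −0.29 after quantile normalization. Their sign depended on scaling and their spots lie near the top of the intensity scale, so they do not settle it either. The median of the combined 40 beta cell genes lay −0.86 log2 from that of all genes under the scaling of the main results. Subtracting a constant from an array cannot change this gap, so median scaling gave the same value by construction. The gap was −0.93 after quantile normalization and −0.86 after normexp. It was also −0.93 with the series matrix values, which look quantile normalized too and add little. For these single arrays, this argues against a scaling constant, or the quantile methods tried, as the whole cause. Fewer beta cells, alone or together with lower expression per cell, stay open, as does a biological difference of another kind between these mice, which was not tested.

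Interferon response genes and lymphocyte markers were both higher in male Tg over male WT (medians 1.31 and 3.18) and both lower in male Tg E2 over male Tg (−1.26 and −1.84), which goes with lymphocytes as a possible source. In female Tg over male Tg, however, the interferon median lay −0.56 log2 (−1.34 to −0.30 over resampled genes) from the lymphocyte median. For these single arrays, this argues against lymphocytes as the whole source at an unchanged interferon response per cell. The range treats genes as independent, which they are not, and measures no variation between mice. Blood left in the islets cannot be told apart from an interferon response in islet cells. In male Tg E2 over male WT the erythrocyte median was −1.22, with 5 of 7 genes at least 2-fold lower. The interferon median there was −0.0360, inside the random lists, which falls short of the drop predicted from blood. The erythrocyte and interferon lists put the 4 arrays in the same order. That order rests on the value of −0.0360, so it decides nothing. Of the interferon genes 19 of 20, of the lymphocyte genes 12 of 14 and of the erythrocyte genes 7 of 9 were well above background on the male WT array, and no gene is shared between lists. A lower interferon response with E2 or in females stays open and was not tested.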
